A study of Mus musculus with 16 samples.

How the data were processed

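Total RNA from a pool of adult mouse retinas and from a pool of postnatal day 1 mouse cortices was hybridised to 1-colour oligonucleotide arrays. Per the labels, about 10 µg of total RNA per array was made into biotin-labelled cRNA, and each array received an aliquot of one of these pools. The descriptions of the first-site samples give 350 mice for the retina pool and 19 mice for the cortex pool, with extraction in TRIzol. The first site ran 5 arrays per tissue and another site, called site 2 in the labels, ran 3 arrays per tissue, which makes 16 arrays. The labels give the retina donors as C57/B6 mice, whereas the cortex donors are C57/B6 in the sample descriptions and Swiss-Webster in the series' design text. That conflict is left open here, so strain is 1 of the ways in which the tissues may differ, beside organ and age.

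The deposited values are intensities on a linear scale, 1 number per probe set and array, so the authors had already summarised the probes of each probe set. The summarisation algorithm, the background handling and any scaling are not given in the sources used here. The array medians ran from 45.7 to 216, a 4.73-fold range, so no common scaling of the arrays was visible in the deposited intensities. No value was below 0.

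The table held 12488 probe sets on each of the 16 arrays. The 66 control probe sets were left out of the tests, which leaves 12422. Gene names came from the platform annotation and were updated through Entrez identifiers to the RefSeq table of assembly GRCm38.p6, in which 10817 of the probe sets with a single symbol were found. Of the tested probe sets, 10833 had 1 gene symbol, 396 had several and were never named, and 1193 are unnamed here. The single-symbol probe sets covered 8251 genes, of which 2073 had more than 1 probe set. Where a gene is represented by 1 probe set, it is the one with the highest mean over the 16 arrays. Among genes with several probe sets called between the tissues, 43 of 625 had calls in opposite directions at the first site and 11 of 338 at site 2. No coordinates are given, because no genome build is named for these values.

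Values were turned into log2(intensity + 16), and each array was centred on its median. Differences are therefore on the log2(intensity + 16) scale, which understates the change of dim probe sets. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with two-sided moderated tests and Benjamini-Hochberg adjustment over all probe sets tested, at a threshold of 0.05. The retina and cortex arrays of each site were fitted on their own. The difference between sites within each tissue, and the interaction of tissue and site, came from a single fit over all 16 arrays with a mean per tissue and site. Intensities printed for single genes were scaled so that each array's median is 100 and are given as mean ± SD over the arrays of a group.

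Per the design text, the arrays of a group are aliquots of a single RNA pool, so the p-values measure only the technical spread between arrays, and nothing here measures the spread between animals. The number of arrays limits the precision. Background was judged from 13 control probe sets with no added target (dap, lys, phe and yeast probe sets). The highest of them on each array ran from 8.8 to 38.3 in deposited intensity, and between 68.5% and 78.8% of probe sets lay above it. Where every array of the dimmer group was at or under that level, the fold is given as a lower bound ("at least"), computed with the dim values raised to it. This floor was chosen after seeing the data.

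Gene sets were 24 lists for the cell types of retina and newborn cortex, for other cells a dissection could carry and for broad processes. They were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and again with an estimated correlation. Genes named in the text are the 12 with the largest difference in each direction at the first site (adjusted p under 0.05, 1 symbol, no overlap between the tissues' arrays), up to 4 members per list with the largest difference and the member that moved most against its list, 5 genes per direction for the interaction and 3 per direction for each difference between sites. The tests, the lists, this rule and most alternatives were fixed before the data were examined.

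The alternatives were pseudocounts of 1 and 50, no centring, quantile normalization, the probe sets above the median signal only, no intensity trend, the replicate number as a block, all 16 arrays in one fit, centring on the 6097 probe sets called at neither site, an estimated correlation or the mean of all probe sets of a gene for the lists, and leaving out each array in turn. Scaling each array to a median of 100 before the pseudocount was added after seeing the data. The procedure was tested on simulated arrays drawn from the real means and array brightness, with a single spread per probe set pooled over the groups. Among 12422 probe sets, 100 were changed 2-fold and 100 were changed 4-fold. For the comparison at the first site, 84 of 100 and 94 of 100 of these were recovered, with 10 false calls. For site 2 the numbers were 47 and 86 of 100 with 6 false calls, and for the interaction 39 and 83 of 100 with 6 false calls. For the difference between sites they were 68 and 91 of 100 with 3 false calls in retina, and 67 and 88 of 100 with 9 false calls in cortex. The simulated arrays left out the larger spread of cortex at site 2. They also changed fewer probe sets than any real comparison called, so these rates need not hold for the real arrays.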

Results

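The series measured transcript levels in adult mouse retina and in newborn mouse cerebral cortex on 16 1-colour oligonucleotide arrays. The retina arrays numbered 5 at the first site and 3 at site 2, and so did the cortex arrays. The stated purpose was to assess how much the measurements vary between replicates on one platform and between sites. Each group consists of repeated aliquots of a single RNA pool. The deposited intensities had array medians between 45.7 and 216, and the summed intensity per array ran from 2478880 to 8639520. Genes are named by symbol, each read from the probe set with its highest mean over the 16 arrays.

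At the first site, the largest differences toward adult retina included genes of rod phototransduction. Pdc, which encodes the photoreceptor regulator phosducin, was at least 195-fold higher in retina. Gnat1, the rod transducin alpha subunit, had a scaled intensity of 10599 ± 742 (SD, n = 5) in retina and 24.6 ± 3.1 (SD, n = 5) in cortex. It was higher by 8.08 ± 0.07 on the log2 scale (SE), Sag, rod arrestin, by 8.06 ± 0.09 and Pde6g, the inhibitory subunit of the rod phosphodiesterase, by 7.74 ± 0.16. Pde6b, the catalytic beta subunit of that enzyme, was at least 139-fold higher. Rom1, an outer segment disc protein, was at least 131-fold higher and Rcvrn, the calcium sensor recoverin, at least 102-fold higher. The limma adjusted p of these 7 genes ran from 4.7e-20 to 1.6e-15. The rule by which they were named required all 5 retina arrays to lie above every cortex array. Another probe set of Pdc differed by -0.02 ± 0.16.

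The remaining 5 of the 12 genes with the largest difference toward retina followed. Tulp1, needed for protein transport to the outer segment, was higher by 7.16 ± 0.20 on the log2 scale and Guca1a, a guanylate cyclase activator, by 6.95 ± 0.09. Cnga1, the rod cyclic nucleotide-gated channel, was at least 40.3-fold higher. Reep6, a membrane trafficking protein, was higher by 6.19 ± 0.08 and Neurod4, a neurogenic transcription factor, at least 38.4-fold higher.

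The 12 genes with the largest difference in the other direction were led by Fabp7, the fatty acid binding protein of radial glia, which was lower in retina by a log2 difference of -5.86 ± 0.08 (SE), with scaled intensities of 85.4 ± 3.8 in retina and 5832 ± 644 in cortex (SD, n = 5 each). Dcx, the microtubule-associated protein doublecortin, differed by -5.50 ± 0.08 and Sox11, a transcription factor of immature neurons, by -5.30 ± 0.10. Tbr1, a transcription factor of early-born cortical neurons, differed by -4.61 ± 0.09, Nnat, the imprinted gene neuronatin, by -4.81 ± 0.11 and Cd24a, a surface protein of immature neurons, by -4.58 ± 0.07. Neurod6, a transcription factor of cortical projection neurons, was at least 19.4-fold lower in retina, Chl1, a neural cell adhesion molecule, at least 38.1-fold lower, and the forebrain interneuron transcription factors Dlx1 and Dlx2 at least 14.7-fold and 15.2-fold lower. Nrgn, the postsynaptic protein neurogranin, differed by -4.41 ± 0.16 and Vcan, the matrix proteoglycan versican, by -4.27 ± 0.14. The limma adjusted p of these 12 genes was at most 1.0e-12. Another probe set of Chl1 differed by 0.04 ± 0.16.

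Over all probe sets tested at the first site, 5850 of 12422 passed the threshold, 2725 higher and 3125 lower in retina. A difference of at least 2-fold was reached by 1878 of them, 890 higher and 988 lower. Without centring the majority turned, with 2351 higher and 2062 lower. The retina and cortex arrays did not overlap for 37.9% of probe sets, where chance gives 0.794%.

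Per the design text, site 2 measured aliquots of the same pools with 3 arrays per tissue, although its sample descriptions give no pool details. At this site genes named above differed in the same directions. Gnat1 was higher in retina by 7.84 ± 0.20 on the log2 scale (SE), Sag by 7.57 ± 0.22 and Pde6g by 7.52 ± 0.18, and Pde6b was at least 146-fold higher. Dcx differed by -5.29 ± 0.19, Sox11 by -5.96 ± 0.28 and Fabp7 by -4.99 ± 0.22, and Neurod6 was at least 28.6-fold lower. The difference was smaller than at the first site for Fabp7 and for Nnat (-3.54 ± 0.17), with limma interaction adjusted p of 0.026 and 0.00063. At this site 4043 probe sets passed the threshold, 2069 higher and 1974 lower in retina, of which 2150 differed at least 2-fold, 1082 higher and 1068 lower. The arrays of the 2 tissues did not overlap for 44.2% of probe sets, where chance gives 10%. Cortex replicate 2 of this site was dimmer than every other array and stood apart from the other 2. Without it, 5946 probe sets passed, 3300 higher and 2646 lower, and without centring of the arrays 781 did, 347 higher and 434 lower.

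The differences between the tissues at the 2 sites were closely related across probe sets. Pearson's r was 0.900, Spearman's rho 0.788 and the slope of site 2 on the first site 0.965 over 12422 probe sets, which are not independent replicates. The sign was shared by 76.0% of probe sets. Of the 1878 probe sets called at least 2-fold different at the first site, 1864 had the same sign at site 2 and 1686 were also called there in that direction. Both sites called 3568 probe sets, 3549 in the same direction and 19 in opposite directions. Those higher in retina at both sites numbered 1792, against 454 for independent lists, and those lower at both numbered 1757, against 497. The arrays of the sites are separate but the RNA pools are shared per the design text, so this relation holds for these pools.

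**Figure D1:**
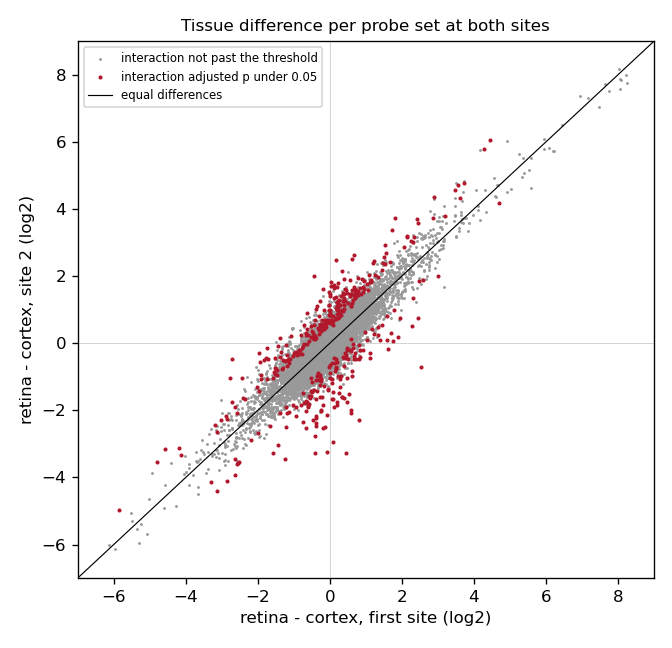
Each point is 1 of 12422 probe sets, with the log2 difference between retina and cortex at the first site on the horizontal axis and at site 2 on the vertical axis; the line marks equal differences and red points are the 418 probe sets whose difference differed between the sites (limma interaction, adjusted p under 0.05). The differences of the sites correlated with a Pearson's r of 0.900, and Kcna1 is the red point at 2.52 and -0.72.

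The lists of retinal neuron types were higher in retina as sets at the first site. All 23 measured rod photoreceptor genes were higher in retina at both sites, with a median log2 difference of 5.95 at the first site (camera adjusted p = 1.1e-23). Of the 9 cone genes, 6 were higher, among them the cone transducin subunit Gnat2 (5.37 ± 0.15, SE) and the short-wave opsin Opn1sw (4.91 ± 0.15). Rxrg, a nuclear receptor of cones that is also made in other tissues, was lower by a log2 difference of -1.70 ± 0.18 (camera adjusted p of the list = 0.0015). At site 2 Rxrg did not pass (-0.64 ± 0.32, limma adjusted p = 0.18). All 5 bipolar cell genes were higher at the first site (adjusted p = 0.00034), including Pcp2 (2.72 ± 0.17, and 1.40 ± 0.11 on its other probe set) and the transcription factor Isl1 (1.96 ± 0.10). At site 2, 4 of the 5 passed. Car8 was higher by 2.28 ± 0.09 at the first site and by 0.50 ± 0.17 at site 2 (limma adjusted p = 0.051, interaction adjusted p = 3.3e-06). For amacrine and horizontal cells 11 of 17 genes were higher and 2 lower (adjusted p = 0.00077). The eye field transcription factor Pax6 was higher by 3.00 ± 0.11, while Stx1a, a presynaptic syntaxin of many neurons, differed by -2.96 ± 0.07. Pax6 was higher by 1.99 ± 0.16 at site 2 (limma interaction adjusted p = 0.0028). Of the 9 ganglion cell genes 8 were higher (adjusted p = 3.5e-05), with the neurofilament gene Nefh at 2.74 ± 0.11 and the surface protein Thy1 at 1.77 ± 0.09.

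Lists of glial and supporting cells of the eye were higher in retina as well. Of 10 Mueller glia genes 7 were higher and 1 lower (adjusted p = 0.00012), with Rlbp1, the retinaldehyde binding protein, at 3.10 ± 0.07 on the log2 scale (SE), Glul, glutamine synthetase, at 2.91 ± 0.09 and Car2, carbonic anhydrase 2, at 4.12 ± 0.06. Another probe set of Glul differed by 0.17 ± 0.12. The pigment epithelium list had 7 of 10 genes higher and 1 lower (adjusted p = 0.0015), among them the retinal G protein coupled receptor Rgr, at least 6.07-fold, and the retinol dehydrogenase Rdh5, 2.63 ± 0.14. Its member that went the other way, Ttr, the carrier transthyretin that choroid plexus also makes in quantity, differed by -0.30 ± 0.11. That call was lost under 6 alternatives, including without retina replicate 3 or 5 or cortex replicate 1 or 5. Of 11 lens genes 8 were higher and 3 did not pass (adjusted p = 0.0002). The crystallin genes Cryaa, at 3.06 ± 0.12, and Cryba1, at least 5.74-fold, were among them. With an estimated correlation the lens call was lost (adjusted p = 0.066).

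Newborn cortex was higher for neuronal growth and for cell division. Of 35 neurite growth and migration genes 33 were lower in retina and none higher (adjusted p = 2e-17), and of 17 cortical projection neuron genes 14 were lower and none higher (adjusted p = 4.4e-08). Id2, an inhibitor of basic helix-loop-helix factors that upper layer neurons express, differed by -2.83 ± 0.09 on the log2 scale (SE). Of 43 proliferation genes 30 were lower in retina and 1 higher (adjusted p = 2.0e-05). Ccnd2, a cyclin of cortical progenitors, was at least 10.7-fold lower, and Rrm2, the ribonucleotide reductase subunit of S phase, differed by -2.91 ± 0.14. The member that was higher in retina, Hmgb2, a chromatin protein, differed by 0.43 ± 0.12. Of 24 genes of meningeal fibroblasts and mural cells 18 were lower in retina and 1 higher (adjusted p = 3.5e-05), with the collagen gene Col4a1 at -2.10 ± 0.07 and the proteoglycan gene Dcn at -2.19 ± 0.10.

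Lists of glycolysis, stress, imprinted and ribosomal protein genes passed too at the preset correlation. Of 19 glycolysis genes 18 were higher in retina (adjusted p = 9.7e-11). Hk2, a hexokinase, was higher by 5.58 ± 0.15 on the log2 scale (SE), Eno2, the neuronal enolase, by 2.50 ± 0.08 and Slc2a1, the glucose transporter GLUT1, by 2.44 ± 0.12. Another probe set of Hk2 differed by -0.38 ± 0.20. The other hexokinase gene of the list, Hk1, went the opposite way by -0.90 ± 0.14. Among immediate early and stress genes 19 of 29 were higher and 5 lower (adjusted p = 0.00034), with the heat shock gene Hspa1b at 3.67 ± 0.11, the immediate early gene Fos at 2.70 ± 0.09 and the Kruppel-like transcription factor gene Klf6 at -1.86 ± 0.08. Another probe set of Fos differed by 0.29 ± 0.18. Imprinted genes were lower for 13 of 18 and higher for 2 (adjusted p = 0.0047, and adjusted p = 0.17 with an estimated correlation). The noncoding RNA gene Meg3 differed by -2.26 ± 0.07, and by -4.93 ± 0.09 on its other probe set, whereas Impact, a regulator of translation, was higher by 1.53 ± 0.16. Of 36 cytosolic ribosomal protein genes 15 were lower and 21 did not pass (adjusted p = 0.026, and adjusted p = 0.3 with an estimated correlation), and that call was also lost without centring and with the mean of all probe sets of a gene.

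The other 8 lists did not pass the threshold as sets at the first site, although single members differed. Of 14 GABAergic neuron genes 8 were lower and 5 higher (adjusted p = 0.09, and past the threshold without centring). The neuropeptide gene Sst, made by cortical interneurons, differed by -3.29 ± 0.11 on the log2 scale (SE) and Calb2, the calcium binding protein calretinin that amacrine cells share, by 2.31 ± 0.07. Of 15 neural progenitor genes 7 were lower and 3 higher (adjusted p = 0.21), with Prom1, which photoreceptor outer segments also use, higher by 5.02 ± 0.09. Of 15 endothelial genes 9 were lower and 3 higher (adjusted p = 0.2), of 20 microglia and macrophage genes 10 were lower and 2 higher (adjusted p = 0.092), and of 10 oligodendrocyte genes 3 were lower (adjusted p = 0.21). The oligodendrocyte progenitor receptor gene Pdgfra differed by -1.75 ± 0.09, and its other probe sets by -0.06 ± 0.13 and -0.09 ± 0.20. Of 15 erythroid genes 4 were lower (adjusted p = 0.14), led by the haemoglobin genes Hba-a1 at -2.08 ± 0.07 and Hbb-b2 at -2.06 ± 0.08. The erythroid median changed sign without centring, and the list passed among probe sets above the median signal. The 10 astrocyte genes went both ways, 3 higher and 4 lower, with a median of -0.10 and a mean of 0.05 on the log2 scale (adjusted p = 0.83). Of 64 oxidative phosphorylation genes 24 were higher and 9 lower (adjusted p = 0.1, and past the threshold with quantile normalization or without retina replicate 5).

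**Figure D2:**
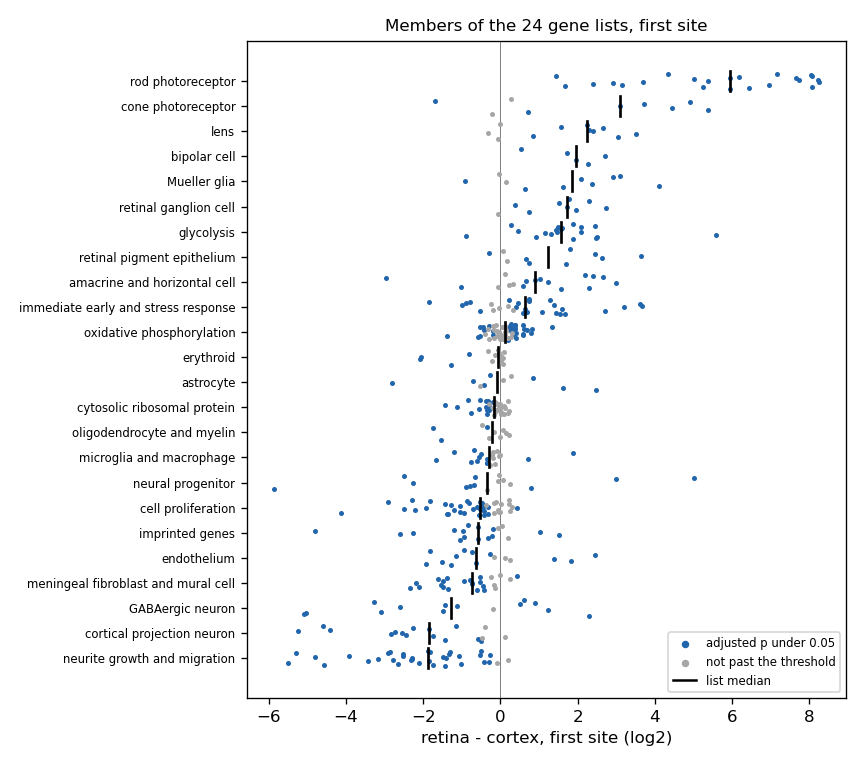
Each point is a measured member of 1 of the 24 gene lists, placed by its log2 difference between retina and cortex at the first site; blue points passed the limma threshold, grey points did not, and black bars are list medians. Rod photoreceptor genes lie farthest to the right with a median of 5.95, and neurite growth and cortical projection neuron genes farthest to the left with medians of -1.89 and -1.86.

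At the first site 10 lists were higher and 6 lower in retina at the preset correlation, and 9 and 4 with an estimated correlation. At site 2 the numbers were 11 higher and 6 lower at the preset correlation, and 0 higher and 3 lower with an estimated correlation. Those 3 were the projection neuron, neurite growth and proliferation lists (adjusted p = 0.03 each). The other 14 had an adjusted p between 0.06 and 0.328 with an estimated correlation. Erythroid genes passed at site 2 (adjusted p = 0.016, and adjusted p = 0.25 with an estimated correlation; not without cortex replicate 2 of that site) and oxidative phosphorylation genes did too (adjusted p = 0.0081, and adjusted p = 0.25 with an estimated correlation), while ribosomal protein genes did not (adjusted p = 0.41). Adjusted over the list alone, the first-site counts of members changed in 4 lists, to 12 higher and 2 lower for amacrine and horizontal cells, 8 and 1 for lens, 0 and 16 for projection neurons, and 1 and 32 for proliferation.

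A minority of probe sets gave a tissue difference that itself differed between sites. Kcna1, a voltage-gated potassium channel, was higher in retina by 2.52 ± 0.18 on the log2 scale (SE) at the first site and lower by a difference of -0.72 ± 0.20 at site 2. Med1, a Mediator subunit, had scaled intensities of 501 ± 57 in retina and 529 ± 55 in cortex at the first site (SD, n = 5 each), and differed by -3.25 ± 0.19 at site 2. Xist, the noncoding RNA of X inactivation, differed by -0.42 ± 0.09 and by -3.26 ± 0.37. Ggnbp2 had an interaction of -2.32. The cell cycle inhibitor gene Cdkn1b passed with all its site 2 retina values at or under the highest no-target control, so the size was not measured, and at site 2 it was at least 2.62-fold lower in retina. Its other probe set had an interaction of -0.24 ± 0.30 (limma adjusted p = 0.8). In the other direction, the beta actin probe set of Actb had an interaction of 2.45. Slc18a3, the vesicular acetylcholine transporter, Esrrb, an orphan nuclear receptor, Avpi1, and Ret, a receptor tyrosine kinase, passed with all their site 2 cortex values at or under the highest no-target control, so the size was not measured. At site 2 they were at least 3.43-fold, 10.2-fold, 4.30-fold and 2.51-fold higher in retina. The limma adjusted p of these 10 ran from 4.3e-09 to 0.011. Aqp4, a water channel of astrocytes, was higher in retina by 1.63 ± 0.10 at the first site, while its difference at site 2 was -0.19 ± 0.16 (limma adjusted p = 0.48) and its interaction had an adjusted p of 2.3e-06. For Actb, another probe set gave tissue differences of 1.09 ± 0.23 and 2.06 ± 0.41 (interaction adjusted p = 0.31), against -0.44 ± 0.16 and 2.01 ± 0.24 for the one named above.

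In all, 418 probe sets passed the interaction test, 257 with a higher and 161 with a lower retina value at site 2 relative to cortex, and 175 reached 2-fold. Without cortex replicate 2 of site 2 the count was 671 (455 higher, 216 lower), without cortex replicate 1 it was 661, and without retina replicate 2 or 3 of site 2 it was 213 or 212. The count of higher values was 168 without retina replicate 3 and 151 without cortex replicate 1 of the first site. The count fell to 34 without centring (13 higher, 21 lower), where all probe sets moved by a median of -0.14, to 129 when arrays were centred on unchanged probe sets (55 higher, 74 lower) and to 255 without an intensity trend. Quantile normalization gave 215 higher and 230 lower.

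Between sites, aliquots of what the design text gives as the same RNA pool differed in level for many probe sets, some of them alike in both tissues. Adam28, a metalloprotease gene, had scaled intensities of 21.7 ± 3.3 in retina at the first site (SD, n = 5) and 258 at site 2 (n = 3), and of 23.4 ± 6.7 and 284 in cortex. A4galt, a glycosyltransferase gene, was at 75.3 and 509 in retina and at 94.2 and 492 in cortex. Gnb1, the transducin beta subunit, was at 7405 and 504 in retina and at 2332 and 153 in cortex, so its difference between the tissues was 1.68 ± 0.15 and 1.64 ± 0.24 on the log2 scale (SE) at the respective sites. Another Gnb1 probe set changed between sites by -0.85 ± 0.10 in retina and -0.12 ± 0.10 in cortex (limma adjusted p = 0.48), with tissue differences of 2.60 ± 0.07 and 1.88 ± 0.16 and an interaction adjusted p of 0.008. A further one changed by -1.42 ± 0.25 and -1.51 ± 0.25, with tissue differences of -0.19 ± 0.18 and -0.11 ± 0.30. In retina, Pip5k1c was higher at site 2, and Xist and Akap9, an anchoring protein, were lower. In cortex, Gsdme, a gasdermin, was higher, and Actb and the phosphatase gene Dusp8 were lower. Another probe set of Gsdme differed between sites in cortex by 0.48 ± 0.17 (limma adjusted p = 0.059).

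Over all probe sets, 4437 differed between sites in retina, 2882 higher and 1555 lower at site 2, and 680 reached 2-fold. In cortex 2076 differed, 1281 higher and 795 lower, and 233 reached 2-fold. Without cortex replicate 2 of site 2 the cortex count was 4976, with 2176 higher and 2800 lower. Without centring the counts were 290 in retina (113 higher, 177 lower) and 79 in cortex (52 higher, 27 lower). The balance of directions also followed the centring, at 2202 higher and 1935 lower in retina and 1110 and 1147 in cortex with quantile normalization, and at 3343 and 775 in retina and 1236 and 323 in cortex when arrays were centred on unchanged probe sets, where all probe sets moved by a median of 0.19 and 0.13. The site differences of the tissues correlated across probe sets (Pearson's r of 0.641, Spearman's rho of 0.630). Of the probe sets called in both tissues, 1439 of 1476 had the same direction.

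Replicate arrays of a group were close to each other in 3 of the 4 groups. The median SD per probe set was 0.185 on the log2 scale for retina and 0.178 for cortex at the first site (n = 5 each), and 0.138 for retina at site 2 (n = 3). For probe sets above the median signal the SDs were 0.142, 0.139 and 0.120. Correlations across probe sets between replicates lay between 0.983 and 0.990, between 0.980 and 0.988, and between 0.989 and 0.991. Cortex at site 2 had a median SD of 0.353 (n = 3) and correlations between 0.940 and 0.989. Its median SD was 0.229 with quantile normalization, 0.236 with arrays scaled first, 0.243 above the median signal and 0.126 without its replicate 2. That array had the lowest median intensity, 45.7, and a ratio of the 5' to the 3' Gapdh control probe sets of 0.603, where the other 15 arrays had at least 1.05.

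**Figure D3:**
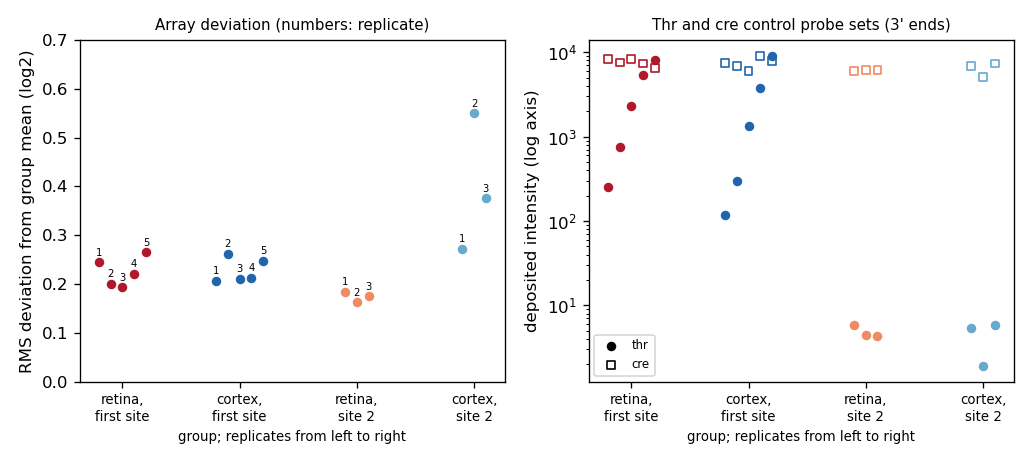
Left, the root mean square deviation of each array from its group mean over all probe sets (log2 scale), with replicate numbers; right, deposited intensities of the 3' thr and cre control probe sets on each array (log axis). Cortex replicate 2 of site 2 has the largest deviation at 0.550, and the thr control runs from 118 to 9154 at the first site while the cre control stays between 5142 and 9130 on all 16 arrays.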

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

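The tests of brightness with the pseudocount, of control signals, of ratios of 5' to 3' signal, of other probe sets of the same genes and of splits of the arrays were chosen after the result was seen, and so was the use of the count without cortex replicate 2 of site 2 as a test.

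Cortex replicate 2 of site 2 stood apart from the other 2 cortex arrays of its site, with 66 probe sets at least 4-fold lower and 33 at least 4-fold higher than their mean. Low brightness together with the pseudocount was argued against as the whole explanation. With arrays scaled first and probe sets above the median signal only, the array's highest correlation with another of these arrays was 0.912. The lowest among replicates of the other groups was 0.976. A part was left open, since scaling first lowered the median SD of this array's group from 0.353 to 0.236. A wrongly labelled array prepared like the 10 first-site arrays was argued against: its thr and trp signals (at most 4.4) and its 5' 18S signal (5.4) lay, probe set by probe set and scaled by array median, below all 10 and at least 2.69 SD below their mean, but its slope on the retina site difference of 0.241, above first-site cortex arrays (at most 0.093) and below the other 2 (0.555 and 0.620), missed the bound set in advance and leaves open a first-site array without these controls. Shorter labelled targets could not be told apart either. The array's Gapdh and Actb ratios of 5' to 3' signal were below those of every other cortex array. Its pyruvate carboxylase ratio (-1.40 on the log2 scale) was below the other 2 cortex arrays of its site (-0.930 and -0.642). That ratio was above all 5 of first-site cortex (-1.65 to -1.42). Over 10 first-site arrays the relation of resemblance to these ratios did not pass (Pearson's r = -0.391, permutation p = 0.3545). Spearman's rho was -0.321 (permutation p = 0.417), and r was -0.148 without the 2 farthest arrays. No biological explanation was tested, since per the design text the array shares its RNA pool with the others.

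The difference between retina and cortex differed between the sites for 418 probe sets by the interaction test. Cortex replicate 2 of site 2 was argued against as the only source of such calls, since 671 probe sets passed without it. Whether these include the 418 is not given here. The count can also rise because the spread shrinks, as the median SD of that group was 0.353 with the array and 0.126 without it. Whether single probe sets or whole genes differed could not be told apart: of the other probe sets of these genes, 63.1% (70 of 111, exact 95% interval 53.4 to 72.0) had the same sign, against 84.8% for the tissue difference at the first site. Since the design text gives the same pools for both sites, no biological explanation was tested. Over 100 splits of the arrays, 3 gave a count of at least 418, the real one included. The others as large gave 1011 and 888 and point to a structure of the samples, not tested further. Both kept the site 2 retina arrays together and placed cortex replicates 1 and 2 of site 2 with the first site. Such splits still hold the retina site difference, so this test could not decide whether chance gave the interaction count.

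The thr and trp control probe sets, which match bacterial transcripts, differed widely between first-site arrays, with highest 3' signals of 9154 for thr and 8516 for trp, whereas the highest thr or trp signal at site 2 was 25.6. The thr signal was 253.6, 743.9, 2284.2, 5419.6 and 8001.2 on retina arrays 1 to 5 and 118.4, 298.8, 1342, 3782.9 and 9154.4 on cortex arrays 1 to 5. Array brightness was argued against, since the cre control spanned 1.53-fold between the same arrays. Carry-over into mouse probe sets was argued against too, since 0 mouse probe sets followed the thr signal with a slope above 0.25 in limma (0 with any slope past the threshold, and 479 with a slope of either sign and any size at an unadjusted p under 0.05). No biological explanation was tested, and the protocol behind these signals is not given in the sources used here.

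The interaction was 2.45 on the log2 scale for Actb, -3.244 for Kcna1, -3.182 for Med1, -2.844 for Xist and -2.318 for Ggnbp2. The fitted values of 1.955 for Slc18a3, 1.905 for Esrrb, 1.884 for Avpi1, 1.81 for Ret and -2.664 for Cdkn1b do not measure a size, since the dimmer tissue at site 2 was at or under the highest no-target control on all 3 arrays. At site 2 the first 4 were at least 3.43-fold, 10.2-fold, 4.30-fold and 2.51-fold higher in retina, and Cdkn1b was at least 2.62-fold lower.

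The 5' control probe set for 18S ribosomal RNA gave up to 6709 in the first-site retina arrays and at most 17.6 at site 2. On first-site cortex array 2 it lay far above the other 4, with a gap of 0.9284 of the range in deposited signal, not scaled for array brightness.

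Of 266 tests for a single distant array in a group of 5, 20 found one, where chance gives about 13.3. On retina array 5 of the first site, low values had gaps of 0.7709 of the range for the bioC control (deposited signal, not scaled, where this array had the lowest median of the 5, 93.4), 0.7654 for Rcvrn, 0.7646 for Gnb3, 0.7393 for Pax6, 0.8307 for Rgr, 0.8086 for Cryaa, 0.7391 for Ndufa2, 0.8025 for Hspa1a and 0.7673 for A4galt. On the same array, high values had gaps of 0.7409 for Lyz2 and 0.7119 for Sox10. Retina array 1 was low for Sag (0.7178) and Cldn11 (0.8276). In cortex at the first site, array 5 was high for Pcp2 (0.7656) and Pip5k1c (0.819) and low for Tfap2a (0.7512), array 2 was high for Tyrp1 (0.8151) and low for Cox6a2 (0.7444), and array 3 was low for Rrm2 (0.809).

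Splits of the arrays into groups of the same sizes reassign aliquots of the pools. They test only the technical spread between arrays, so chance differences between pools or animals remain open. For the tissues at the first site the real split gave 5850 probe sets, 1 of 100 splits gave as many and the highest other gave 1. That argues against a chance assignment of these arrays. The 10 splits at site 2 are too few for a share under 0.05 (real value 4043, highest other 0). A chance assignment of arrays was also argued against for the site difference in retina (4437, highest other 2 among 56 splits). In cortex the real split gave the largest count (2076, 1 of 56 splits). The highest other in cortex gave 1943 and placed replicate 2 of site 2 with the first site, so the real count was not clearly set apart.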

How the results depend on the processing

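Scaling each array before the pseudocount was chosen after seeing the data. Of the results named singly, 5113 values under alternatives kept direction and side of the threshold, or moved within the replicate spread, 89 lost their call, 20 gained one, 37 values without a test moved and 8 reversed. Of the values that answer a comparison, 205 were counted as staying and 34 as moving, by a wider bound. By it the site 2 tissue count of 4043 stayed at 5946 without cortex replicate 2 of site 2. The interaction count of 418 stayed at 552 without cortex replicate 3 of site 2. Some of the 205 could not move, such as the correlation of tissue differences without centring, which shifts all probe sets of an array alike. The first-site tissue count stayed between 4413 and 6037 under all alternatives that tested all probe sets. It was 4367 where only the probe sets above the median signal were tested. Where no cause is given, the cause was not tested. Signal over background limits the dim probe sets.

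Without centring, array brightness stays in the values. The site 2 tissue count was then 781 (733 at 2-fold or more), the interaction count 34, the site counts 290 in retina and 79 in cortex, and the median SDs 0.303 and 0.224 for retina and cortex at the first site and 0.155 and 0.832 at site 2. The interaction count was 255 without an intensity trend and 129 with centring on unchanged probe sets. The correlation of tissue differences between sites was 0.858 with a pseudocount of 1, 0.915 with 50 and 0.923 for probe sets above the median signal. With pseudocounts of 1 and 50 the median SD was 0.223 and 0.140 for cortex at the first site and 0.185 and 0.102 for retina at site 2. Above the median signal it was 0.142 for retina and 0.139 for cortex at the first site and 0.120 for retina at site 2, where quantile normalization gave 0.125. With an estimated correlation 3 lists passed at site 2. The higher interaction calls numbered 155 with a pseudocount of 50 and 135 without an intensity trend, and the lower site calls in retina 967 above the median signal.

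Leaving out 1 array at a time gave 212 to 671 interaction calls, 1480 to 4976 site calls in cortex, correlations between sites of 0.871 to 0.900, and median SDs of 0.0974 to 0.126 for retina and 0.126 to 0.395 for cortex at site 2. Every fit pooled the spread over its groups, also where this left a group with 2 arrays. Same-numbered arrays of the tissues at a site did not pair on mouse probe sets. Their deviations from the group means correlated by -0.187 to 0.080, and not every array correlated best with its own number. At the first site these arrays did share a rank of the thr control signal, which rose with the number in both tissues. With the replicate number as a block the counts were 5771 and 4335 for the tissues at the first site and site 2, 347 for the interaction, and 16 and 17 for the lists. The site counts, 4437 in retina and 2076 in cortex, were the same as without a block. Each block lay within 1 site, so blocking could not change the estimated site differences and is no check of them.

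Some small effects changed sign. Hmgb2 at site 2 was -0.020 without centring, -0.0048 with quantile normalization and -0.060 to 0.120 on leaving out 1 array. Hk1 at site 2 was -0.577 to 0.240 on leaving out 1 array. The GABAergic list had a signed -log10 p of 0.067 at the first site above the median signal.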

Other observations

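The gene groups of this part, their camera tests, the sex chromosome genes looked up and the comparison of other probe sets were chosen after the result was seen.

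In 5 other gene groups, formed by symbol stem, most of the members that passed limma's test were lower in adult retina than in newborn cortex. As groups they passed camera at site 2 with the preset correlation only, and with an estimated correlation 0 of 265 groups passed at either site (6 at the first site and 4 at site 2 at an unadjusted p under 0.05). Of 13 cadherin genes, which encode cell adhesion molecules, 9 were lower at the first site and 10 at site 2, and none was higher. Cdh13 differed by -4.18 ± 0.14 on the log2 scale (SE, n = 5 per tissue) at the first site and by -3.11 ± 0.15 (n = 3) at site 2, in limma with adjusted p = 3.1e-13 and 3.1e-07. Of 13 Sox transcription factor genes 9 were lower at each site, with Sox4 at -2.91 ± 0.08 at the first site. The 8 members of the Dlx stem include the noncoding Dlx1as and Dlx6os2. Of the 6 Dlx transcription factor genes 4 were lower at each site, and Dlx3 was higher at site 2 (adjusted p = 0.043). Of 12 Klf genes 8 and 9 were lower and Klf9 was higher, by 1.58 ± 0.10 at the first site. Of 31 collagen genes 15 and 12 were lower and 3 and 2 higher, with Col9a1 higher by 1.01 ± 0.11 and Col3a1 at least 3.31-fold lower at the first site.

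Among 265 such groups of at least 5 genes, camera at the preset correlation passed these 5 at site 2 (adjusted p = 0.0179 for Cdh, Sox and Klf, 0.0411 for Dlx and 0.0486 for Col). At the first site their adjusted p were 0.11, 0.115, 0.355, 0.115 and 0.147 for Cdh, Sox, Klf, Dlx and Col, and 0 of 265 passed (32 at an unadjusted p under 0.05).

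Among 4 genes of the sex chromosomes looked up, Xist and Eif2s3y differed between sites, where 35.7% of all probe sets differed in retina and 16.7% in cortex. Xist was lower at site 2 in retina by -3.74 ± 0.24 on the log2 scale (SE, limma adjusted p = 8.7e-10) and in cortex by -0.90 ± 0.24 (adjusted p = 0.014). Eif2s3y was higher by 0.48 ± 0.14 (adjusted p = 0.011) and 0.56 ± 0.14 (adjusted p = 0.01). The differences of Uty were -0.21 ± 0.24 and 0.33 ± 0.24 in retina and cortex, and neither Uty nor Kdm5d passed.

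For genes with a called probe set, their other probe sets with signal above the median had the same sign in 84.8% of 660 cases for the tissue difference at the first site and in 83.1% of 520 at site 2. For the site difference the share was 53.6% of 642 in retina and 57.5% of 358 in cortex.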
